A study of Mus musculus with 12 samples.

How the data were processed

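Liver RNA from 12 male mice on the C57BL/6J background was measured on Affymetrix gene arrays, 1 array per mouse. The labels name 6 wild-type (WT) mice and 6 mice with the K289R knock-in of the gene for LRH-1, and sex, tissue and feeding were the same in both groups. All mice were fasted for 24 h and refed for 6 h before liver collection, per the labels' protocols. Total RNA was extracted with TRIZOL, cleaned on RNeasy columns, amplified with the Ambion WT expression kit and labelled with biotin, per the labels' protocols.

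The deposited values are linear summarized intensities, 1 per probe set and array, as judged from their range and from their lack of whole-number steps. Affymetrix Expression Console made them, per the submitters' processing notes. Its version, the summarization method, the background correction and the normalization are not given in the sources used here. The deposited intensities had median values of 26.8 to 29.2 and upper quartiles of 78.6 to 85.0 across the 12 arrays, so they had been brought to a common scale before deposit. No detection call per probe set was used here, so dim probe sets were tested with the rest. For arrays, the number of arrays limits the precision, and no counting error applies.

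The table held 35556 rows. In the platform annotation 21789 rows had 1 gene symbol, 1621 had several and 12146 were not listed. Rows with several symbols or none were left out of gene results. Of the rows with 1 symbol, 21698 matched the RefSeq gene table (assembly GRCm38.p6) by gene ID. That table was used only for names and for the order of neighbouring genes, and no coordinates are given because the files name no genome build. A gene with over 1 probe set (999 of 19938 genes) was represented by the probe set with the highest mean log2 value over all 12 arrays.

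Because the values were linear, log2 was taken first, without a pseudocount. K289R was compared with WT by limma (version 3.58.1, in R 4.3.3) with lmFit and eBayes, on all 12 arrays without covariates. A gene was called changed at a two-sided Benjamini-Hochberg adjusted p under 0.05 over the 19938 genes. Every adjusted p of a gene given below comes from this limma fit unless another setting is named. Means ± SD are over the linear intensities of 6 arrays, whereas log2 fold changes and fold changes come from means of log2 values.

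Gene lists were fixed before the data were examined: 25 lists of pathways and functions and 11 lists of cell type markers, 36 in all. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists tested. A list with under 4 measured members was not tested, which left 35 lists. Beside the count of members passing over all genes, the count adjusted over the list alone is given. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in one direction, were alternatives. For the gene sets of the closing section, an exact permutation test of the mean log2 level of a set over all choices of the WT arrays (924 with 12 arrays) was added. The list of LRH-1 target genes was drawn up with knowledge of published work on this mouse line.

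Genes were named by a rule fixed before the data were examined. It took the 12 highest and 12 lowest called genes by log2 fold change, passing over predicted genes, microRNAs, snoRNAs and receptor families. It also took the measured genes of a fixed set of LRH-1 and lipid biology. In each list it took up to 4 members with the smallest p that passed over all genes or over the list alone, otherwise 2 members.

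Other settings tried were equal array medians, quantile normalization, leaving out dim genes, the mean of all probe sets of a gene, a trended and robust variance model, array weights, the replicate number as a block, all rows of the table, and each array left out in turn. Leaving out arrays that stood apart was added after the data were examined. The replicate numbers name different mice, so the main comparison had no block. The labels gave no slide or scan date, so array batches were not analysed here.

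The procedure was tested on simulated data made from the means and residual spread of these 19938 genes. It called 89 of 100 genes changed 1.5-fold and 97 of 100 genes changed 2-fold in a simulated comparison of K289R with WT. Of its 193 calls, 7 were unchanged genes. A simulated shift of the fatty acid oxidation list was found, and 0 of 32 lists without a shifted member were called. The simulated genes were drawn independently of each other. This check therefore says nothing about false calls of lists whose members are correlated, as in the real arrays. Figures were drawn with matplotlib 3.10.9.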

Results

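The study measured liver transcripts in mice with a point mutation of LRH-1, a nuclear receptor encoded by Nr5a2 that regulates bile acid, cholesterol and glucose metabolism in the liver. The K289R knock-in replaces a lysine with an arginine and removes a site at which the small protein SUMO is attached to the receptor. Livers of 6 WT and 6 K289R male mice were compared after a 24 h fast and 6 h of refeeding, a state in which the liver takes up glucose and makes fatty acids. The comparison asks which liver transcripts differ between the genotypes in the refed state. Each array came from a separate mouse. Values are probe-set intensities in linear units, and pairwise correlations of log2 values between arrays ran from 0.979 to 0.991. The first principal component held 25.1% of the variance, and scores of the groups overlapped along it, from -20.2 to 0.44 in WT and from -6.04 to 20.7 in K289R.

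Transcripts of other tissues and of the acute phase set a few arrays apart within each group. Pancreatic acinar markers, which encode digestive enzymes, had a mean log2 intensity of 8.42 on array K289R 1 and 8.97 on array K289R 3, against 4.34 ± 0.09 (SD, n = 6) in WT. Carboxypeptidase B (Cpb1) measured 449 and 892 on those arrays and at most 10.6 on any WT array. Acute phase genes, which the liver induces in inflammation, averaged 9.70 on array WT 1 and 9.80 on array WT 3 on the log2 scale, whereas the other WT arrays lay between 8.48 and 8.72. Array K289R 4 was the highest of its group, at 9.03 against 8.43 to 8.86 on the other K289R arrays. Its Saa2 intensity of 228 was near the 246 and 254 of WT 1 and WT 3, but its Saa1, Mt1 and Mt2 were lower. Serum amyloid A (Saa1) reached 96.1 and 62.9 on WT 1 and WT 3, against 7.53 to 9.40 on the other WT arrays. On K289R 4 Saa1 measured 28.3. Mt2 measured 2415 and 1078 on WT 1 and WT 3 and 285 on K289R 4. Mt1 measured 699 and 2038 on WT 1 and WT 3 and 149 on K289R 4. The same WT arrays had the lowest means of the de novo lipogenesis list, 8.53 and 8.72, whereas K289R 4 had 9.27. Skeletal muscle transcripts, a list drawn up after the arrays were examined, were highest on WT 1 (6.97) and K289R 3 (5.81).

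**Figure D1:**
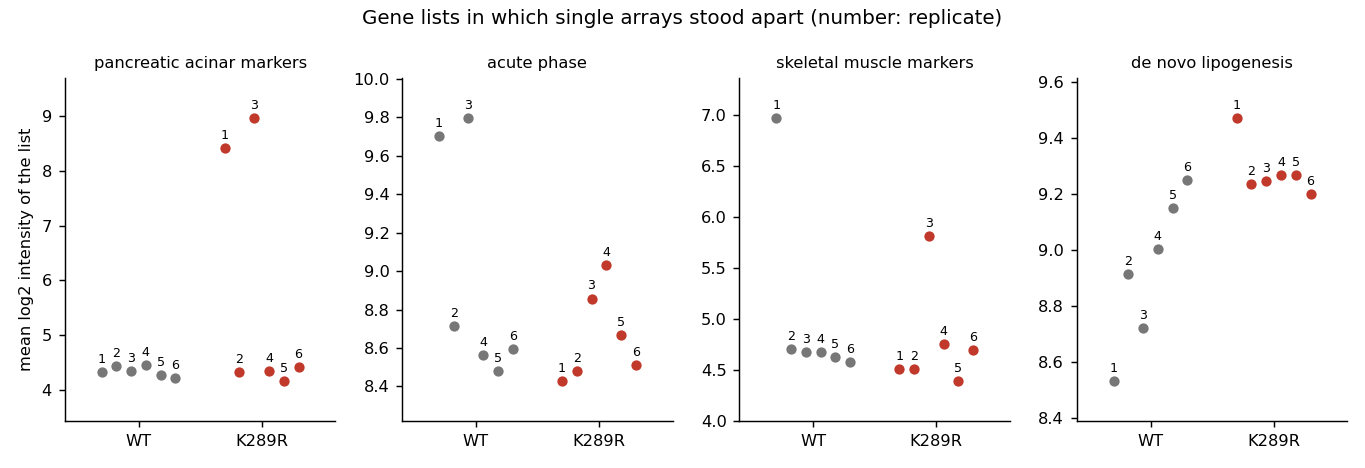
Mean log2 intensity of 4 gene lists (vertical axes) on each array, with WT arrays in grey and K289R arrays in red and the replicate number above each point. Acinar markers were high on K289R 1 and 3, acute phase genes were high on WT 1 and 3, muscle transcripts on WT 1 and K289R 3, and lipogenesis genes were lowest on WT 1 and 3.

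K289R livers differed from WT livers in 114 of 19938 genes, of which 96 were higher and 18 lower. The gene with the largest rise was Ctse, which encodes the endolysosomal aspartic protease cathepsin E. Its intensity was 18.8 ± 3.99 (SD, n = 6) in WT and 447 ± 92.7 (n = 6) in K289R, a rise of at least 23.8-fold (adjusted p = 1.49e-11, probe set 10349648). The WT value lay below the median of every array (26.8 to 29.2), where signal was not told from background here, so folds against such values are written as at least the measured one. Asparagine synthetase (Asns), which makes asparagine from aspartate and glutamine, rose 14.8-fold from 54.1 ± 15.2 to 779 ± 80.4 (n = 6 each, adjusted p = 5.32e-11). The steroidogenic cytochrome P450 Cyp17a1 rose 4.24-fold (adjusted p = 9.33e-06), and the ammonium transporter Rhbg rose 3.01-fold (adjusted p = 1.36e-07). Meg3, a maternally expressed imprinted noncoding RNA, rose 2.98-fold (adjusted p = 1.53e-08).

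Among the other genes with the largest rises were Rgs16, a regulator of G protein signalling (4.72-fold, 95% CI 2.73 to 8.17), and the cytochrome P450 genes Cyp2b9 (at least 5.48-fold, from 19.9 in WT) and Cyp2c38 (2.86-fold). The phosphate cotransporter Slc34a2 rose 2.89-fold, the glutamate receptor subunit gene Gria3 at least 2.61-fold (from 14.3 in WT) and Tedc2 2.53-fold. The Rgs16 call did not pass without WT 1 and 3 (adjusted p = 0.0589), and that of Cyp2c38 did not without all 4 arrays (adjusted p = 0.0659). All 6 K289R arrays lay above all 6 WT arrays for these genes except Cyp2b9, for which 4 did. Rises were larger than falls: 17 genes rose by at least 2-fold and 1 fell by as much. For 98 of the 114 genes the arrays of the groups did not overlap at all. Chance gives this for 0.216% of genes that were not selected. The 114 genes were selected by their difference on these same arrays, so that share is no measure of chance for them. At an unadjusted p under 0.05 there were 2399 genes, 1280 higher and 1119 lower, where 996.9 were expected by chance.

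The count of changed genes was 75 without K289R 1 and 3, the arrays with acinar transcripts, and 65 when WT 1 and 3 were left out as well. Of those 65 genes, 50 were among the 114. All 114 genes kept their direction, on arrays that had also served to choose them.

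**Figure D2:**
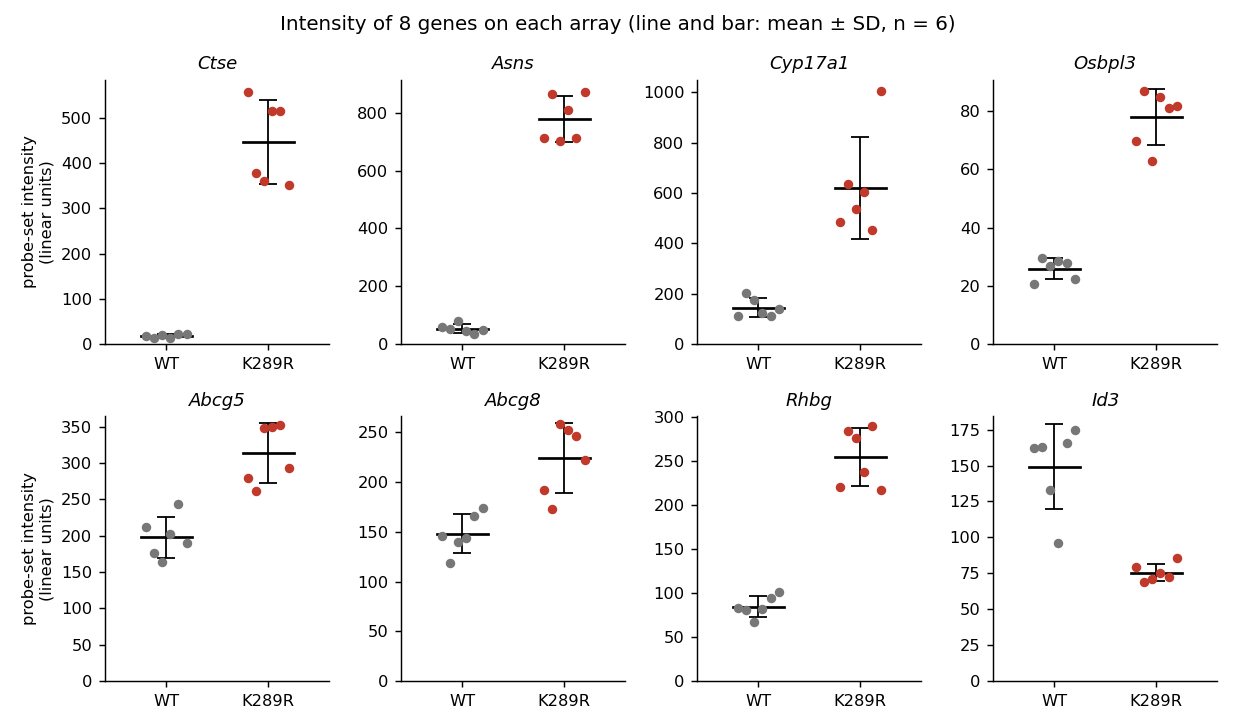
Probe-set intensity in linear units (vertical axes, from 0) of 8 genes on the 6 WT arrays (grey) and the 6 K289R arrays (red), with the mean and the SD. All 6 K289R arrays lie above all WT arrays for Ctse, Asns, Cyp17a1, Osbpl3, Abcg5 and Rhbg, 5 of 6 do for Abcg8, and all 6 lie below for Id3.

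Nr5a2 itself did not change: its intensity was 303 ± 27.1 in WT and 324 ± 18.4 in K289R (SD, n = 6 each, log2 difference 0.10, adjusted p = 0.582, probe set 10358210). Its probe set measures the amount of transcript and not the base change, so it does not check the genotype. Prox1, a corepressor that binds LRH-1, had a log2 difference of 0.05 (adjusted p = 0.914).

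Among known LRH-1 targets, Osbpl3, Cyp17a1, Abcg5 and Abcg8 rose in K289R livers. Osbpl3, an oxysterol-binding protein that acts in lipid droplet and triglyceride metabolism, rose by at least 1.59 on the log2 scale, from 26.0 ± 3.64 to 77.9 ± 9.52 (SD, n = 6 each, adjusted p = 1.36e-07, probe set 10544660). Abcg5 and Abcg8, which together form the transporter that secretes cholesterol into bile, rose 1.59-fold (adjusted p = 0.00426) and 1.51-fold (adjusted p = 0.0164). Of the 12 measured LRH-1 targets, 4 rose, none fell and 8 did not pass. The same 4, Cyp17a1 included, passed when adjusted over the list alone. The list shifted upward with a median log2 fold change of 0.31 (camera adjusted p = 8.49e-07; adjusted p = 0.00647 with an estimated correlation). Because Osbpl3 and the transporters were known from published work on this line, the list is not independent evidence of its direction. Without Osbpl3, a setting chosen after the data were examined, its median was 0.29 (adjusted p = 0.0300 with an estimated correlation). That setting kept Abcg5 and Abcg8, so it does not free the list of genes known from the published work. The classical targets Nr0b2 (SHP), Cyp7a1 and Cyp8b1 had log2 differences of 0.29, 0.42 and 0.34, with adjusted p of 0.456, 0.496 and 0.357. The Abcg8 call did not pass without K289R 5 (adjusted p = 0.0506), nor without K289R 1 and 3 (adjusted p = 0.0560) or WT 1 and 3 (adjusted p = 0.0936). Without WT 1 and 3 the list median was 0.18. Without all 4 arrays Abcg5 did not pass (adjusted p = 0.0573), and the list had an adjusted p = 0.0504 with an estimated correlation.

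In the reverse cholesterol transport list, Abcg5 and Abcg8 were the members that rose among 15. The cholesterol efflux transporters Abca1 and Abcg1 had log2 differences of -0.06 (adjusted p = 0.804) and -0.03 (adjusted p = 0.858), and the HDL receptor Scarb1 one of 0.14 (adjusted p = 0.601). The list median was 0.03 (camera adjusted p = 0.0148; adjusted p = 0.234 with an estimated correlation). Among 12 oxysterol-binding proteins Osbpl3 rose over all genes, and Osbpl1a (log2 difference 0.29) passed when adjusted over the list alone. That list had a median of 0.06 (camera adjusted p = 0.0250; adjusted p = 0.134 with an estimated correlation) and did not pass without Osbpl3 (adjusted p = 0.342). No member of the cholesterol synthesis list passed among 20 measured, over all genes or over the list alone. Its median was 0.03 (camera adjusted p = 0.238; adjusted p = 0.0297 without K289R 1 and 3, but adjusted p = 0.711 there with an estimated correlation), with the largest difference in Tm7sf2 (0.33, adjusted p = 0.281).

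The de novo lipogenesis list shifted upward with the preset correlation, with a median log2 fold change of 0.28 (camera adjusted p = 3.50e-11; adjusted p = 0.134 with an estimated correlation), and no member passed over all genes. Of its 20 measured members 19 had a positive log2 fold change, and 10 rose when adjusted over the list alone. These included the lipogenic regulator Thrsp (2.32-fold, adjusted p = 0.0561 over all genes), the lipid droplet protein Pnpla3 (log2 difference 0.68), malic enzyme Me1 (1.43-fold) and ATP citrate lyase Acly (1.39-fold). Fatty acid synthase (Fasn) measured 1715 ± 442 in WT and 2423 ± 357 in K289R (SD, n = 6 each, adjusted p = 0.187 over all genes). Acetyl-CoA carboxylase (Acaca), Elovl6 and Scd1 had log2 differences of 0.31, 0.43 and 0.41, and passed over the list alone. Srebf1, the sterol-responsive transcription factor of this pathway, had a difference of 0.25 (adjusted p = 0.422) and did not pass. The WT spread was wide, with a list mean of 8.93 ± 0.27 against 9.28 ± 0.10 in K289R (SD, n = 6 each), and the median was 0.18 without WT 1 and 3.

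Of 24 genes of lipid droplets and triglycerides, Osbpl3 rose over all genes and 6 rose when adjusted over the list alone. Beside Osbpl3 and Pnpla3 these included the phosphatidate phosphatase Lpin1 (2.38-fold) and the fatty acid transporter Cd36 (2.20-fold). Over all 24 the median was 0.10 (camera adjusted p = 2.71e-06; adjusted p = 0.0241 with an estimated correlation), and without Osbpl3 the estimated correlation gave an adjusted p = 0.0929. It gave 0.0762 without WT 1 and 3. Lipid droplet coat and lipoprotein genes had small differences, with log2 values of 0.09 for Plin2, 0.04 for Cidec and 0.12 for Mttp, none of which passed.

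Of 12 gluconeogenesis genes 4 rose over all genes and 8 did not pass. The list median was 0.19 (camera adjusted p = 2.94e-06; adjusted p = 0.104 with an estimated correlation), and the estimated correlation gave an adjusted p = 0.0231 without WT 1 and 3, 0.152 without K289R 1 and 3 and 0.0504 without all 4 arrays. The genes that rose were the alanine aminotransferase Gpt2 (1.56-fold), the aspartate aminotransferase Got1 (1.42-fold), the coactivator Ppargc1a (1.42-fold) and glucose-6-phosphatase G6pc (1.83-fold, adjusted p = 0.0218). The G6pc call did not pass without K289R 1 and 3 (adjusted p = 0.124), nor in 4 of the 12 fits that left out 1 array. In the glycolysis list, 6 of 10 members rose when adjusted over the list alone and none over all genes. Among them were the glucose transporter Slc2a2 (1.49-fold), the fructokinase Khk (1.35-fold), the regulatory protein Gckr (1.20-fold), the phosphofructokinase Pfkl (1.21-fold) and pyruvate kinase Pklr (1.49-fold), whereas Tpi1, Pgam1 and Ldha had log2 differences of -0.12, -0.05 and -0.16. Its median was 0.27 (camera adjusted p = 0.000718; adjusted p = 0.0474 with an estimated correlation). That correlation gave an adjusted p = 0.128 without K289R 1 and 3 and 0.0762 without WT 1 and 3.

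Of 20 genes of the insulin and feeding response, 5 rose and 2 fell when adjusted over the list alone. Igfbp1, which insulin represses, rose 2.49-fold, whereas Igfbp2 was 1.51-fold and the insulin-induced Egr1 2.01-fold lower. The Egr1 log2 difference was -1.01 with all arrays and -0.63 without WT 1 and 3. For the whole list the median was 0.21 (camera adjusted p = 0.000797, and adjusted p = 0.105 with an estimated correlation). Because the list mixes genes that insulin represses with genes that it induces, its median gives no direction of an insulin response. Fatty acid oxidation also had a positive median, 0.16 over 22 genes (camera adjusted p = 0.000197; adjusted p = 0.239 with an estimated correlation). Of its members 6 rose when adjusted over the list alone, among them the pantetheinase Vnn1 (1.67-fold), the lipase inhibitor Angptl4 (1.88-fold, and adjusted p = 0.00781 over all genes without WT 1 and 3), Bdh1 (1.26-fold) and the hormone Fgf21 (1.26-fold).

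Cyp39a1, an oxysterol hydroxylase, rose 2.01-fold (adjusted p = 0.00530). When adjusted over the list alone Cyp27a1 (1.19-fold) and the conjugating enzyme Baat (1.17-fold) also rose among 14 genes of bile acid synthesis. That list had a median of 0.13 (camera adjusted p = 0.00448; adjusted p = 0.134 with an estimated correlation) and did not pass without WT 1 and 3 (adjusted p = 0.0791). Abcb4, which moves phosphatidylcholine into bile, rose 1.40-fold (adjusted p = 0.00804). Among 12 bile acid transport genes the organic anion pumps Abcc2 (1.25-fold) and Abcc3 (1.28-fold) passed over the list alone. The transport list had a median of 0.14 (camera adjusted p = 0.000797; adjusted p = 0.134 with an estimated correlation).

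Of 9 measured female-biased liver genes 3 rose: Cyp17a1, Cyp2b9 and the acyl-CoA thioesterase Acot3 (1.59-fold, adjusted p = 0.0404). The list median was 0.14 (camera adjusted p = 0.000197, and adjusted p = 0.0241 with an estimated correlation). Its mean log2 fold change was 0.62, and 6 members did not pass. The median was 0.22 without K289R 1 and 3 and 0.08 without WT 1 and 3. The list was dim, with a mean log2 intensity of 4.09 in WT and 4.71 in K289R. The mean over all genes was 5.28 to 5.33 across the arrays. Cyp2b9 and Acot3 were close to the threshold, and the calls were lost in 7 and 9 of the 12 fits that left out 1 array. Without WT 1 and 3 the list had an adjusted p = 0.0743 with an estimated correlation. Without K289R 1 and 3 neither Cyp2b9 (adjusted p = 0.159) nor Acot3 (adjusted p = 0.0954) passed, and the measured log2 difference of Cyp2b9 was then at least 1.98, against at least 2.45 with all arrays. Male-biased genes had a median of -0.22 over 13 genes and did not pass (camera adjusted p = 0.107). The list passed downward without WT 1 and 3 (median -0.20, camera adjusted p = 0.00159; adjusted p = 0.241 with an estimated correlation), whereas without K289R 1 and 3 its median was -0.08 (adjusted p = 0.239). Leaving out 1 array moved that median between -0.26 and -0.09. Over that list alone, with all arrays, Gstp1 fell by 0.45 and C6 by 0.32 on the log2 scale, whereas Cyp4a12a rose 1.24-fold. Of 17 genes of xenobiotic metabolism Cyp2b9 rose over all genes, and the receptor Nr1i2 (1.30-fold), Nqo1 (at least 1.30-fold) and Cyp3a25 (1.35-fold) rose over the list alone. That list had a median of 0.08 (camera adjusted p = 0.00170; adjusted p = 0.363 with an estimated correlation) and did not pass without WT 1 and 3 (adjusted p = 0.0965).

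Id3, Ccnd1, Xbp1 and Socs3 were among the 18 genes that fell. Id3, an inhibitor of helix-loop-helix transcription factors, was 1.94-fold lower, with 149 ± 29.6 in WT and 75.5 ± 6.13 in K289R (SD, n = 6 each, adjusted p = 0.000711). Cyclin D1 (Ccnd1) was 1.55-fold lower (adjusted p = 0.000907), and Xbp1, a transcription factor of the unfolded protein response, 1.42-fold lower (adjusted p = 0.00548). The cytokine signalling inhibitor Socs3 was 1.43-fold lower (adjusted p = 0.0184). The odorant-binding lipocalin Obp2a fell from 46.4 ± 16.2 to 23.1 ± 6.62, and the lipid transporter Abca3 was 1.78-fold lower, the zinc importer Slc39a4 1.74-fold and the carboxylesterase Ces1b 1.55-fold. Susd4, Sel1l3, the mannosyltransferase Alg12 and the aminopeptidase Rnpep were 1.52-, 1.48-, 1.43- and 1.39-fold lower. The Abca3 fall depended on the arrays used: its log2 difference was -0.83 with all arrays (adjusted p = 0.0452), -1.15 without K289R 1 and 3 (adjusted p = 1.52e-05) and -0.78 without WT 1 and 3 (adjusted p = 0.171). It was lost in 10 of the 12 fits that left out 1 array, and Sel1l3, Obp2a, Alg12 and Socs3 lost theirs in 8, 4, 4 and 1. Without K289R 1 and 3 the calls of Sel1l3 (adjusted p = 0.181), Obp2a (adjusted p = 0.0731) and Alg12 (adjusted p = 0.0917) did not pass, and without all 4 arrays that of Ces1b (adjusted p = 0.0573) did not.

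Of 23 acute phase genes 22 had a negative log2 fold change and Socs3 was the member that passed, though not without WT 1 and 3 (adjusted p = 0.102) or without K289R 1 and 3 (adjusted p = 0.0730). Their median was -0.22 (camera adjusted p = 4.53e-05; adjusted p = 0.400 with an estimated correlation), and it was -0.02 without WT 1 and 3, the arrays with high acute phase transcripts. Of 18 genes of the unfolded protein response Xbp1 passed, and the median was -0.10 (camera adjusted p = 0.00533; adjusted p = 0.396 with an estimated correlation). Without WT 1 and 3 this list had a median of 0.02 and did not pass (adjusted p = 0.626), and the Xbp1 call did not pass without K289R 1 and 3 (adjusted p = 0.0560). Immediate early genes had a median of -0.13 over 14 genes (camera adjusted p = 0.00533; adjusted p = 0.134 with an estimated correlation), with Egr1 passing over the list alone. Cell cycle genes had a median of 0.02 over 21 genes (camera adjusted p = 0.892). Among them Ccnd1 fell over all genes, and over the list alone Pcna (1.21-fold) and Rrm2 (1.39-fold) rose, while Mcm6, dim in both groups, was lower.

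Markers of liver zones and of other cell types gave no shift common to all types. Of 12 pericentral hepatocyte markers Rhbg rose, and the median was 0.07 (camera adjusted p = 0.00131; adjusted p = 0.134 with an estimated correlation). Of 9 periportal markers the aldehyde dehydrogenase Aldh1b1 rose 2.08-fold (adjusted p = 0.000158) and Cyp2f2 fell by 0.27 on the log2 scale over the list alone. The periportal median was 0.11 (camera adjusted p = 0.0182; adjusted p = 0.239 with an estimated correlation), and the list did not pass without K289R 1 and 3 (adjusted p = 0.117). Pancreatic acinar markers had a median of 1.47 over 12 genes, which came from K289R 1 and 3 (camera adjusted p = 1.09e-05; adjusted p = 0.335 with an estimated correlation). Trypsin Try5 and elastase Cela3b had log2 differences of 1.61 and 1.41 that did not pass. Adipocyte markers had a median of 0.22 over 6 genes (camera adjusted p = 0.0393; adjusted p = 0.416 with an estimated correlation), with resistin (Retn) up 1.38-fold, a call lost in 8 of the 12 fits that left out 1 array. Without K289R 1 and 3 their median was 0.01 (adjusted p = 0.726), and Retn did not pass (adjusted p = 0.202).

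Endothelial markers had a median of 0.09 over 12 genes (camera adjusted p = 0.0142; adjusted p = 0.416 with an estimated correlation), and no member passed, Oit3 (0.18) and Stab2 (0.18) being nearest. The list did not pass without WT 2 (adjusted p = 0.111) or without K289R 5 (adjusted p = 0.110). Markers of Kupffer cells (median 0.05, adjusted p = 0.249), stellate cells (median -0.0004, mean 0.05, adjusted p = 0.479) and cholangiocytes (0.07, adjusted p = 0.238) did not pass, and neither did those of lymphocytes (-0.02, adjusted p = 0.496) and neutrophils and monocytes (0.01, adjusted p = 0.762). Among their members with the smallest p were Folr2 (0.20), Cd68 (-0.14), Rgs5 (0.41), Dcn (0.11) and Cd8a (-0.22), all log2 differences that did not pass. Epcam, Muc1, Cd79a, Mmp8 and Cxcr2 did not pass either and were below the median of every array in both groups, so no difference is given for them. Red blood cell markers had 3 measured members and were not tested, with Slc4a1 at 0.09 and Alas2 at 0.13.

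Oxidative phosphorylation had a small positive median of 0.06 over 21 genes (camera adjusted p = 0.00801; adjusted p = 0.400 with an estimated correlation), and Ndufa4 (0.16) and Cox6c (0.13) did not pass. In the one-carbon and methionine cycle, Shmt1 (1.28-fold) and the cystathionine lyase Cth (1.26-fold) rose over the list alone among 15 genes. That list had a median of 0.08 (camera adjusted p = 0.0228; adjusted p = 0.149 with an estimated correlation) and did not pass without all 4 arrays (adjusted p = 0.0945). Amino acid catabolism and the urea cycle (median 0.04, adjusted p = 0.127), the circadian clock (0.11, adjusted p = 0.107) and the interferon response (0.10, adjusted p = 0.109) did not pass. Their nearest members were Oat (0.23), Tdo2 (0.27), Dbp (-0.18), Cry2 (0.17), Gbp3 (0.36) and Irf7 (-0.34). Genes of the SUMO pathway had a median of 0.02 over 13 genes (camera adjusted p = 0.547), with Sumo3 at 0.15 and Senp7 at 0.13. Leaving out 1 array ended the preset call of adipocyte markers in 6 of 12 fits (highest adjusted p = 0.210, without K289R 1) and of the one-carbon list in 2 (0.0573, without WT 6). It ended that of oxidative phosphorylation without K289R 6 (0.0552), oxysterol-binding proteins without WT 2 (0.0579), periportal markers without K289R 3 (0.111) and the unfolded protein response without WT 3 (0.0922). In all, 23 of the 35 tested lists passed with the preset correlation, 20 upward and 3 downward. With an estimated correlation 4 passed: LRH-1 targets, lipid droplets and triglycerides, female-biased genes and glycolysis. When WT 1 and 3 and K289R 1 and 3 were all left out, none of them passed with it. The adjusted p were then 0.0504, 0.133, 0.0651 and 0.205 in that order. These lists are not separate results, since LRH-1 targets share Osbpl3 with the lipid droplet list and Cyp17a1 with the female-biased list.

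**Figure D3:**
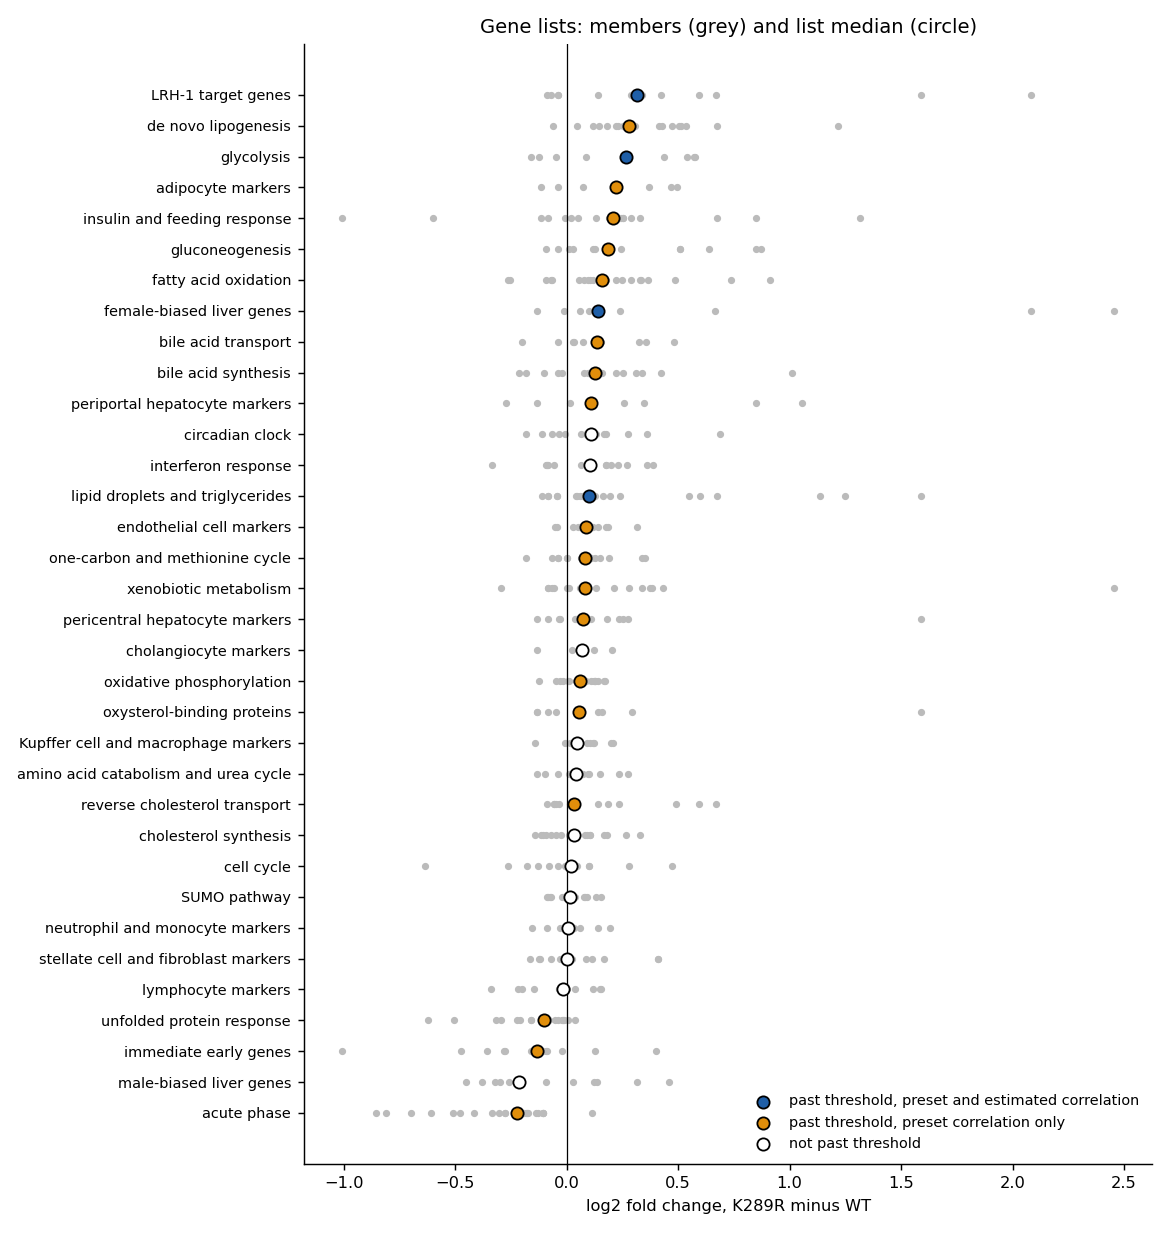
Log2 fold change of K289R minus WT (horizontal axis) for the members (grey points) and the median (circles) of 34 gene lists, ordered by median, blue where the list passed with both the preset and the estimated correlation and orange where it passed with the preset alone. The acinar list, with a median of 1.47, is left out for scale, and LRH-1 targets (0.31) have the highest median of those drawn.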

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

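The tests of the genes near Nr5a2, of the acinar transcripts and of the lipogenesis list were chosen after the results were seen, and the splits of the arrays were planned before. Of 100 splits of the 12 arrays into 6 and 6, drawn from 462 possible ones with the real split among them, 1 gave as many changed genes as the real 114, namely the real one, and the highest other count was 6. For the 96 higher genes that number was 1 (highest other 5), and for the 18 lower genes it was 1 (highest other 5). Chance was therefore excluded at the 5% level for these counts. For the 23 shifted gene lists 2 splits gave as many, and the highest other split gave 27 lists, so a single other split exceeded the real one. The other splits had a median of 7 lists, and with an estimated correlation the real split gave 4 lists and the highest other 0.

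Changed genes were more frequent in a wide neighbourhood of Nr5a2 than elsewhere, but not among the genes closest to it. Of its 300 nearest measured neighbours 6 changed (Gpr39, Ctse, Pm20d1, Snrpe, Rnpep and Rgs16), which is 2% against 0.551% elsewhere (Fisher's exact p = 0.00763), and 2.8% of 2000 windows of that size around other genes held as many. The nearest of the 6, Rnpep, lay 25 measured genes from Nr5a2, and the others lay 52 to 122 genes away. Among the 100 nearest neighbours 1 changed, which is 1% against 0.570% elsewhere (Fisher's exact p = 0.438). With 600 neighbours the p was 0.0220. DNA flanking Nr5a2 that was carried along with the knock-in allele is a candidate explanation for these 6 genes, Ctse among them, but an effect of the mutant receptor on neighbouring genes was not tested and stays open. Of the changed genes with a known place, 94.7% lay outside the window. The window held 300 genes, a small part of those measured, so a large share outside it was likely beforehand. That share does not exclude an effect of flanking DNA on genes elsewhere.

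Acinar transcripts marked arrays K289R 1 and 3. All 12 measured acinar markers lay above all 10 other arrays in both, whereas the other 4 K289R arrays differed from WT by -0.0294 in mean log2 level against a rise of 4.36 in those arrays. These values argue against a rise of acinar transcripts caused by the allele in every liver, and pancreatic tissue in those samples is a candidate source. Why only K289R samples carried it was not tested.

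Lipogenesis genes were lowest on WT 1 and 3, the arrays with high acute phase transcripts. Array K289R 4, with an acute phase mean of 9.03, below the 9.70 and 9.80 of WT 1 and 3, had a lipogenesis mean of 9.27. Without WT 1 and 3 the median log2 fold change of the list was 0.181, against 0.281 with all arrays. The share of the shift that came with the acute phase state and the share that came with the genotype cannot be told apart, because 4 WT arrays remain and the value lies between the bounds set for either reading.

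Single arrays lay far from the other 5 of their group in 17 of 300 groups of 6, measured as the gap to the nearest array over the whole range (above 0.625). Chance flags about 1 in 20 groups, or 15 here. On WT 1 the high ones were Angptl4 (gap share 0.844), Egr1 (0.635) and the stellate cell and fibroblast list (0.638), and the low ones Abcg1 (0.693) and Pmvk (0.753). On WT 3 Sel1l3 (0.689) and Senp7 (0.651) were high, and Abcb4 (0.772) and Nr1i2 (0.711) low. Obp2a was high on WT 4 (0.703). Array K289R 1 was high for Ces1b (0.675), Slc34a2 (0.631) and the de novo lipogenesis list (0.748). Array K289R 3 was high for Gckr (0.636), Plin2 (0.704) and Slc2a2 (0.778), and K289R 4 was low for Sumo3 (0.752). Among probe sets without a single gene, which the comparison of genes does not use, 14 of 13767 differed between K289R and WT, 8 higher and 6 lower.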

How the results depend on the processing

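Leaving out arrays that stood apart was chosen after the data were examined, and the other settings were planned. All 114 genes kept their direction in each other fit of genes, where tested (101 of them without dim genes). These fits reuse the arrays on which the genes were chosen, so a kept direction was likely beforehand and is weak evidence. The count of changed genes was 123 with quantile normalization, 141 with equal array medians and 76 when each probe set of the table was tested. The share of higher genes ran from 76.4% with quantile normalization to 90.1% with equal array medians. Leaving out 1 array at a time gave 81 to 159 changed genes, 66 to 129 higher, 12 to 30 lower, and 20 to 25 shifted lists. Some of these fits also brought calls that all arrays did not give, for Thrsp, Pnpla3, Me1, Acaca, Igfbp1, Egr1, Angptl4, Pcna, Rrm2 and Rgs5 and for the lists of male-biased genes, cholesterol synthesis, interferon response and circadian clock.

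Without K289R 1 and 3 there were 75 changed genes, 62 of them higher. Without those and WT 1 and 3 there were 65, with 54 higher and 11 lower; fewer arrays were fitted. When each row of the table was tested, 60 rows were higher, 8 of them without a single gene. Lower genes numbered 29 with quantile normalization and 31 without dim genes (11322 genes tested). The causes of these differences in count were not tested. Shifted lists numbered 4 with an estimated correlation and 14 with fry. The acute phase list turned from a downward to an upward direction by camera, with medians of -0.0192 without WT 1 and 3 and 0.0137 without all 4 arrays. Acinar markers turned to -0.0349 without K289R 1 and 3 and -0.0443 without all 4, which shows that these arrays carried the shift.

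With the replicate number as a replicate block, 111 genes changed (94 higher and 17 lower), of which 88 were among the 114, and 24 lists shifted. Arrays with the same number had correlations from -0.231 to 0.233, and 1 of 6 WT arrays correlated best with its own number. Dim probe sets lie near background, which limits what can be seen there.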

Other observations

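The genes in this part and the tests of Meg3, Asns and the ChREBP targets were chosen after their values were seen, and the exact permutation tests were added after the fry tests. Beyond the genes named above, K289R livers had higher transcripts of the alpha-arrestins Txnip and Arrdc4, both induced by glucose. Arrdc4 rose from 49.1 ± 9.11 to 101 ± 7.55 (SD, n = 6 each, 2.08-fold, adjusted p = 6.06e-05), and Txnip rose 1.82-fold (adjusted p = 0.0284). The adhesion gene Gldn rose by at least 1.32 on the log2 scale (adjusted p = 4.93e-08) and the axon guidance receptor Robo1 2.35-fold (adjusted p = 0.000277). Coreceptor Klb, through which FGF21 and FGF15 signal, rose 1.52-fold (adjusted p = 0.00519). Endothelial lipase (Lipg) rose 1.51-fold (adjusted p = 0.0428). Whether the calls in this paragraph pass when arrays are left out is not given here. Those of Txnip and Lipg lay near the threshold.

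Meg3 lies in an imprinted cluster of noncoding RNAs. Of its neighbours there, DQ267102 rose 1.69-fold (adjusted p = 0.00152). Mir382 and Mir329, with mean log2 values of 2.62 and 3.03, lay below the lower quartile of every array and are given no difference here. The hypothesis that the other maternal RNAs of the cluster rise with Meg3 was left open. The 42 members other than Meg3, Mir382, Mir329 and the paternal genes had a median log2 fold change of 0.0603, with 30 above 0 (exact permutation p = 0.0281; fry p = 0.0432). Without DQ267102 the exact permutation p was 0.0541 and the fry p 0.0704. Most of the 42 members also lay below the lower quartile of every array. The median, the count above 0 and the p-values therefore rest mainly on signal not told from background. The test decides nothing about these dim members.

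Asns is a target of the amino acid response through ATF4. If that response had risen in general, its other targets should have been higher. The other 26 genes had a median of 0.0616, with 17 above 0 (exact permutation p = 0.00866, fry p = 0.00420), and Gpt2 was the 1 that passed over all genes. Gpt2 had already been called on these same arrays. The set was not tested without it, so its part in these p-values is not known. Members of the set ran from Ddit3 (-0.16) and Chac1 (-0.14) to Slc38a2 (0.36), Vldlr (0.42, adjusted p = 0.0680) and Gpt2 (0.64). A rise near that of Asns (3.89) was not seen in these genes, and the test leaves a small general response open.

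Txnip, Arrdc4, Rgs16 and G6pc are targets of ChREBP, a transcription factor that responds to glucose. Rgs16 is also one of the changed neighbours of Nr5a2, for which flanking DNA is a candidate explanation. Its call did not pass without WT 1 and 3 (adjusted p = 0.0589), nor did that of G6pc without K289R 1 and 3 (adjusted p = 0.124). The hypothesis was that other ChREBP targets rise as a group. The 12 measured targets outside the changed genes and the lipogenesis list had a median of 0.255, with 10 above 0 (exact permutation p = 0.0152; fry p = 0.0218). Without WT 1 and 3 the median was 0.162, with 8 above 0, and the exact permutation test did not pass (p = 0.0667) although fry did (p = 0.0286). Both tests ask whether the set moved, and not whether it moved more than other genes. Because 20 gene lists shifted upward with the preset correlation, they cannot tell ChREBP targets from other metabolic genes. Pklr, Khk, Slc2a2 and Gckr had already been found higher over the glycolysis list alone, and Fgf21 over the fatty acid oxidation list alone. Higher ChREBP activity in refed K289R livers stays a hypothesis. It was found and tested on the same data and rests in part on WT 1 and 3.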
